A study of Mus musculus with 6 samples.

How the data were processed

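Cells of the follicle's dermal sheath (DS), of its papilla (DP) and of the surrounding dermis as fibroblasts (DF) were sorted by flow cytometry from the back skin of female CD1 mice at postnatal day 16, with 2 biological replicates of each population. Per the labels, RNA from the sorted cells was amplified by the NuGEN Ovation system before library construction and Illumina sequencing. The markers used for sorting are not given in the sources used here. The deposited values are RPKM per gene, made by the authors, with a column per library and no pooling of replicates. They are not whole numbers and were not treated as counts. The processing notes name Salmon 1.9.0, DESeq2 1.28.1 and the genome build GRCm39 without a role or an order. The annotation, the filters and the read totals are not given in the sources used here. The reference held here is of an earlier build, so no coordinates are reported, and it served only to give gene types for 24506 of the 24529 gene IDs.

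The summed RPKM were 2187559 and 2124705 in the DF libraries, 1460553 and 1176256 in DP and 1586603 and 1493504 in DS. Relative depth was estimated from low values, since 1 read gives the smallest RPKM above 0 for a gene of given length. The most frequent ratio to DF replicate 2 was taken over genes low in both libraries, and its inverse is the depth. That ratio was searched near a first estimate from RPKM and transcript lengths. From 68 to 155 genes lay at it, and no uncertainty was computed. Relative depth ranged from 0.39 for DS replicate 1 to 1.0 for DF replicate 2. Whole reads were not recovered, so no counting intervals or limits for values at 0 are given.

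Groups, comparisons, tests, gene lists and most alternative settings were fixed before the data were examined. Values were analysed as log2(RPKM + 1) for the 14664 genes with at least 1 RPKM in at least 2 libraries. All 6 libraries entered 1 linear model per gene with a mean per population, in limma 3.58.1 under R 4.3.3, with variances moderated by eBayes with a trend (3 residual and 2.62 prior degrees of freedom). The 3 pairwise comparisons were tested two-sided, with Benjamini-Hochberg adjustment over the genes of each comparison. A gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1. SD values are between the 2 libraries of a population, in RPKM, and SE values come from the moderated fit, on the log2 scale. A gene enriched in a population was called higher than in both others. Each population's 2 comparisons share libraries, so the number expected for independent lists and the number in simulated data without effects were also computed.

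The 32 gene lists covered contraction, calcium and vasoactive signalling, markers of the 3 populations, matrix and adhesion, signalling pathways, cell state and markers of other cell types of skin. They were written from general knowledge before the data were examined, and share some genes. Lists with at least 5 tested genes (31 of them) were tested by camera in limma, two-sided, with a preset correlation between genes of 0.01, and again with the correlation estimated from the data. The estimated form changes more than the correlation, as values given with the alternatives show. Camera compares a list with all other genes, so its direction can differ from the sign of the list's own median. For each list the members called higher or lower were counted, with adjustment over all tested genes and adjusted over the list alone.

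Genes were named by a rule fixed beforehand. It took in each comparison and direction the 10 called genes with the largest difference, at least 5 RPKM in the higher population and no overlap between the libraries, 16 focal genes in every comparison, at most 4 called members of each list with the largest difference, and 10 enriched genes per population. Not every gene so picked is described, 1 focal gene is not reported here, and small RNA genes are given as counts. Genes outside the rule are said to be chosen after their values were seen.

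Each choice was changed alone. The alternatives fixed beforehand were a pseudocount of 0.1, no filter, a filter at 5 RPKM, rescaling of each sample to the same sum, median-ratio scaling, eBayes without a trend, a fit of only the 2 groups compared, a replicate block, no fold minimum, an estimated correlation and leaving out each of the 6 libraries. Rescaling to the same sum without Mir6236 or without the 100 highest genes, and leaving out small RNA genes, were added after seeing the data. Ranges of adjusted p over the alternatives leave out the estimated correlation, which is given apart. The procedure was tested on simulated data with the observed spread, in 20 draws of 200 changed genes. Recovery was 6.85% at a log2 difference of 1 and 53.3% at 2, with a false share of calls of 4.14%. Calls there were counted at an adjusted p under 0.05 without the fold minimum. Far fewer genes changed than were called in the data, so recovery in the data can differ. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.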

Results

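RNA sequencing measured the transcripts of 3 mesenchymal cell populations sorted by flow cytometry from the back skin of female CD1 mice at postnatal day 16, when the hair follicles enter catagen, the phase in which the lower follicle regresses. Dermal sheath (DS) cells form a layer around the follicle, dermal papilla (DP) cells form the signalling cluster at its base, and dermal fibroblasts (DF) lie in the dermis. Each population had 2 biological replicates, which gives 6 libraries. The markers of the sort gate are not given in the sources used here, so a gene described below may have been part of the gate. Values are RPKM, read numbers divided by transcript length and by library depth. Of 24529 genes listed, 20179 were above 0 in at least 1 library and 14664 reached 1 RPKM in at least 2 libraries and were tested. Read totals are not given in the sources used here, and no counting interval was set. The depth of each library relative to DF replicate 2, set at 1.0, was estimated from ratios of low values. It was 0.71 for DF replicate 1, 0.63 and 0.50 for the DP libraries and 0.39 and 0.46 for the DS libraries. Low values were therefore least precise in DS. Across genes, which are not independent replicates, log2(RPKM + 1) correlated between replicates with Pearson's r of 0.941 in DF, 0.938 in DP and 0.933 in DS, and between populations with r from 0.739 to 0.798. The first principal component held 47.1% of the variance and the second 35.6%.

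The populations also differed in how a few genes shared the summed RPKM. RPKM divides by transcript length, so a short gene, such as a microRNA gene, takes a larger share of this sum than of the reads. The microRNA gene Mir6236, singled out after its values were seen, held 77.1% and 74.6% of the summed RPKM in the DF libraries, 57% and 46.6% in DP and 60.1% and 56.7% in DS. Of the rest, 5 matrix genes also chosen after their values were seen (Col1a1, Col1a2, Col3a1, Sparc and Mfap4) held 21.3% and 17.2% in DF, 0.287% and 0.306% in DP and 0.873% and 0.812% in DS. The median log2 difference over all tested genes was 0.532 for DS minus DF, 0.712 for DP minus DF and -0.169 for DS minus DP. Division by median-ratio factors brought these medians to 0.003, 0.016 and 0.004. Differences near those shifts depend on the scaling, and each gene named below as higher or lower kept its direction with median-ratio scaling.

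DS was compared with DF to ask which transcripts set the sheath, the contracting layer that the series is about, apart from fibroblasts of the same skin. Most tested genes of the smooth muscle contractile machinery were called higher in DS. Acta2, which encodes smooth muscle actin (gene ID 11475), averaged 1042 ± 79.8 RPKM in DS and 2.24 ± 0.228 in DF (SD, n = 2 libraries per population here and below), a log2 difference of 8.33 (SE 0.15, limma adjusted p = 4.84e-05). Tagln, an actin-binding protein of smooth muscle, averaged 155 ± 3.24 RPKM in DS and 1.27 ± 0.867 in DF (log2 difference 6.16, SE 0.46, adjusted p = 0.00056). Mylk, the kinase of myosin light chain, averaged 281 ± 10.8 RPKM in DS and 53.9 ± 12.6 in DF (log2 difference 2.38, SE 0.20, adjusted p = 0.000806). Actg2 (log2 difference 7.10) and Tpm2 (5.77) were also higher, while Myh11 reached only 4.28 ± 0.318 RPKM in DS and 0.568 ± 0.0377 in DF (1.75, adjusted p = 0.00633). Of the 34 tested genes of the contractile list, 26 were higher in DS and 1 was lower (camera adjusted p = 1.04e-06, and adjusted p = 0.319 with an estimated correlation). Beside these, pericyte and vascular smooth muscle markers were split, with 5 of 16 higher and 4 lower (adjusted p = 0.606), and 5 of 10 arrector pili muscle markers were higher and 1 lower (adjusted p = 0.0568). The arrector pili list was called up with median-ratio scaling (0.00825), no filter (0.0165), a filter at 5 RPKM (0.0306), without Mir6236 (0.0328) and without the 100 highest genes in the total (0.0122), as adjusted p within a range up to 0.348, and had adjusted p = 0.434 with an estimated correlation. Ranges here and below leave out the estimated correlation, which is given apart. Among calcium handling genes, Casq2, the calcium-binding protein of the sarcoplasmic reticulum, averaged 147 ± 2.98 RPKM in DS and 0.154 ± 0.121 in DF (log2 difference 7.01, adjusted p = 5.12e-05), and Itpr1, a calcium release channel, was higher by 2.89. That list had 16 of 41 members higher and 2 lower and did not pass the test (adjusted p = 0.0923). With median-ratio scaling 8 were higher and 2 lower, and the list was called up with that scaling (0.0313), no filter (0.0085) and without the 100 highest genes in the total (0.0379), as adjusted p within a range up to 0.226. The calcium list had adjusted p = 0.718 with an estimated correlation.

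Both endothelin receptor genes were higher in DS. Ednrb (gene ID 13618) averaged 1623 ± 143 RPKM in DS and 3.27 ± 0.852 in DF, a log2 difference of 8.58 (SE 0.20, adjusted p = 5.02e-05), and Ednra (gene ID 13617) averaged 240 ± 18.3 and 17.6 ± 0.279 RPKM, a difference of 3.69 (SE 0.13, adjusted p = 8.45e-05). Ednrb is also a gene of melanocytes, whose marker list was lower in DS for 5 of 12 members, among them Dct and Tyrp1, and higher for 1, Mitf, which was named after its value was seen (adjusted p = 5.12e-05, and adjusted p = 0.35 with an estimated correlation). The ligand gene Edn1 (gene ID 13614) was low throughout, with 3.99 ± 0.436 RPKM in DS and 0.815 ± 0.643 in DF (log2 difference 1.50, SE 0.30, adjusted p = 0.0125). The call of Edn1 ended with median-ratio scaling (adjusted p = 0.0775), without the 100 highest genes in the total (adjusted p = 0.0854) and without DS replicate 2 (adjusted p = 0.058), within a range from 0.00404. Edn3, another ligand gene, averaged 0.101 ± 0.102 RPKM in DS and 2.55 ± 0.713 in DF (log2 difference -1.68, adjusted p = 0.00557). The endothelin list as a whole had 5 of 10 members higher and 1 lower, or 2 and 1 with median-ratio scaling, and did not pass (adjusted p = 0.0895).

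More adhesion genes were higher than lower in DS. Itga11, a collagen-binding integrin chain, averaged 218 ± 9.38 RPKM in DS and 5.89 ± 0.237 in DF (log2 difference 4.99, adjusted p = 9.17e-05), and Itga8 (4.58) and Vcl, which encodes the focal adhesion protein vinculin (4.04), were higher too. Of 34 genes for integrins and focal adhesion proteins, 19 were higher and 1 lower, or 13 and 2 with median-ratio scaling (camera adjusted p = 0.0283, and adjusted p = 0.47 with an estimated correlation). The surface protein gene Cd200 averaged 642 ± 150 RPKM in DS and 2.05 ± 0.307 in DF (log2 difference 7.70, SE 0.23, adjusted p = 6.07e-05). Chchd10 (7.60), Pde6h (7.11) and Corin (5.67), a serine protease of the follicle mesenchyme, were also higher. Of 20 dermal sheath markers, 17 were higher and 1 lower (camera adjusted p = 1.36e-05, and adjusted p = 0.319 with an estimated correlation). That list names the sorted population and holds Acta2 and both receptor genes, so its direction is not independent of the sort or of the contractile list.

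More interstitial matrix genes were lower in DS than were higher. Col1a1, the main chain of type I collagen (gene ID 12842), averaged 523 ± 3.17 RPKM in DS and 32801 ± 3934 in DF, a log2 difference of -5.96 (SE 0.16, adjusted p = 5.12e-05). Eln, which encodes elastin (log2 difference -7.06), Lum (-6.86) and Col3a1 (-5.99) were also lower, while Col11a1, a chain of the fibrillar type XI collagen, was higher at 423 ± 65.2 against 2.62 ± 1.15 RPKM (6.90, adjusted p = 0.000105). Of 43 genes for fibrillar collagens and interstitial matrix, 7 were higher and 21 lower (camera adjusted p = 1.36e-11, and adjusted p = 0.319 with an estimated correlation). Markers of reticular, fascial and adventitial fibroblasts were higher for 5 of 25 genes and lower for 12, with Pcolce2 (-6.98), Clec3b (-6.31) and Cd34 (-6.11) among the lower ones (camera adjusted p = 4.3e-09, and adjusted p = 0.183 with an estimated correlation). Papillary fibroblast markers were higher for 4 of 17 genes and lower for 7, or 2 and 8 with median-ratio scaling, such as Dpp4 (-5.76) and Crabp1 (-4.65), with camera adjusted p = 0.00107 and adjusted p = 0.397 with an estimated correlation. Crabp1 is also on the dermal papilla list. The chemokine gene Ccl11 averaged 0.162 ± 0.0938 RPKM in DS and 350 ± 33.1 in DF (log2 difference -8.24, SE 0.18, adjusted p = 5.02e-05). Leukocyte markers moved with these matrix genes, higher for 1 of 19 and lower for 9, with C1qc and Csf1r at 9.20 ± 2.98 and 9.30 ± 1.17 RPKM in DF and below 1 in DS (camera adjusted p = 7.64e-07, and adjusted p = 0.319 with an estimated correlation).

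Signalling and stress lists had members on both sides between DS and DF, and fewer on the higher side with median-ratio scaling. Of 46 Wnt pathway genes, 9 were higher in DS and 11 lower, or 7 and 16 with median-ratio scaling, including the targets Apcdd1 (log2 difference -4.48) and Axin2 (-3.40) and the inhibitor Sfrp1 (-3.84), with camera adjusted p = 4.4e-05 and adjusted p = 0.463 with an estimated correlation. BMP and TGF-beta genes were higher for 10 of 38 and lower for 10, or 4 and 14 with median-ratio scaling, with the BMP inhibitor Nog higher, at 22.9 ± 1.83 RPKM in DS and 0.495 ± 0.194 in DF, and Bmp4 lower (log2 difference -3.69). Camera placed this list below the other genes (adjusted p = 0.00296, and adjusted p = 0.47 with an estimated correlation), with a median of 0.05 and a mean of -0.09. Genes of immediate early response and dissociation stress were higher for 7 of 33, such as the heat shock gene Hspb1 (3.19), and lower for 12, such as Jun (-2.64) and Atf3 (-2.11), or 4 and 17 with median-ratio scaling, with camera adjusted p = 3.54e-05 and adjusted p = 0.319 with an estimated correlation. Matrix proteases were higher for 8 of 30 and lower for 8, or 6 and 11 with median-ratio scaling. Mmp11 averaged 2788 ± 504 RPKM in DS and 45.8 ± 18.7 in DF (log2 difference 5.94, adjusted p = 0.000159), and Mmp27 was lower (-5.05). Camera placed the protease list below the other genes although its median of 0.01 and mean of 0.14 were above 0 (adjusted p = 0.0119, and adjusted p = 0.397 with an estimated correlation). That call ended with median-ratio scaling (adjusted p = 0.0701, within a range from 0.00194) and without the 100 highest genes in the total (adjusted p = 0.0603). Dermal papilla markers were higher for 12 of 38 genes and lower for 12, or 10 and 15 with median-ratio scaling, with a median of 0.24 and a mean of -0.04. Their test below the other genes (adjusted p = 0.00341, and adjusted p = 0.539 with an estimated correlation) ended with median-ratio scaling (adjusted p = 0.316, within a range from 0.000118) and without the 100 highest genes in the total (adjusted p = 0.243).

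In all, 3899 of the 14664 genes differed between DS and DF, 3027 higher and 872 lower in DS, and 7969 had an unadjusted p under 0.05. With median-ratio scaling 2630 genes differed, 1174 higher and 1456 lower, of which 1174 and 871 had the same call as in the deposited scaling. Of the 31 fixed lists tested, 3 were called up and 12 down, and none kept its call with an estimated correlation, where the lowest adjusted p was 0.183 and 4 lists had an unadjusted p under 0.05. Adjusted over the list alone, the counts of the lists above were the same except 9 lower proteases and 8 higher stress genes. Among the 100 largest called differences, 34 were of small RNA genes, for which 32.3% of the gene and population combinations were at 0 in one replicate and at 5 RPKM or more in the other, against 0.0981% for other genes. An exact permutation of 2 libraries against 2 cannot give a two-sided p below 0.333, so every p rests on the spread that limma shares across genes and populations.

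**Figure D1:**
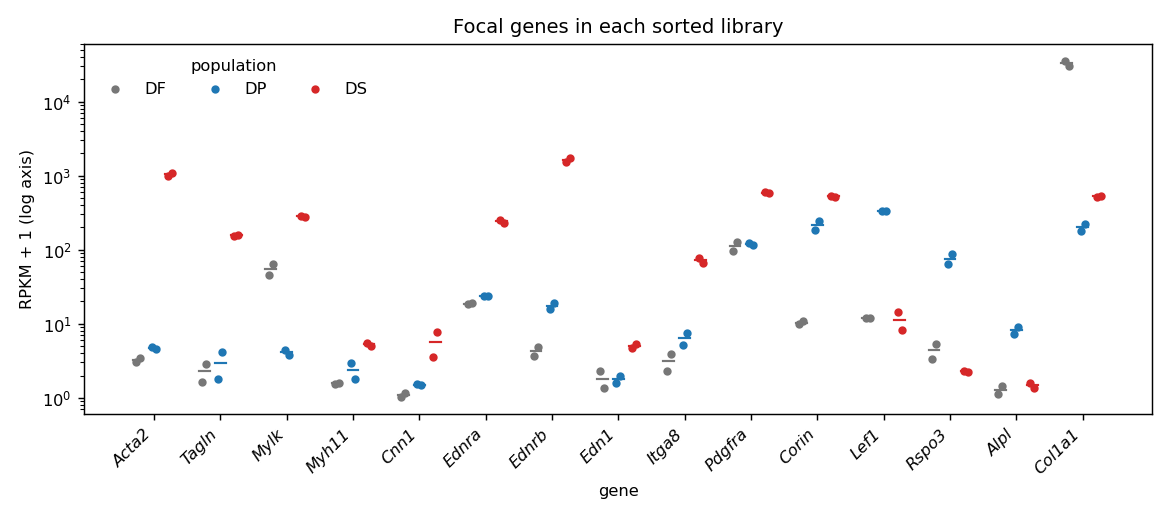
RPKM + 1 on a log axis for 15 of the 16 focal genes in each library, with a point per library and a line at the mean of the 2 libraries of each population. Acta2 and Ednrb stand at means of 1042 and 1623 RPKM in DS, Lef1 at 333 RPKM in DP and Col1a1 at 32801 RPKM in DF.

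DP was compared with DF to ask which transcripts mark the papilla at the onset of regression. Most dermal papilla markers were higher in DP. Crabp1, a cytoplasmic retinoic acid binding protein (gene ID 12903), averaged 2519 ± 235 RPKM in DP and 46.6 ± 21.3 in DF, a log2 difference of 5.80 (SE 0.38, adjusted p = 0.000327). Lef1, a transcription factor of the Wnt pathway (gene ID 16842), averaged 333 ± 5.49 RPKM in DP and 11.1 ± 0.0117 in DF (log2 difference 4.79, SE 0.27, adjusted p = 0.00024). Serpine2, a serine protease inhibitor (6.07), Spp1, which encodes osteopontin (6.13), and Prdm1 (5.68) were higher by more than Lef1. Corin (4.37), Rspo3 (4.12) and Alpl (2.67) were also higher, Alpl from a lower level of 7.18 ± 1.35 RPKM in DP and 0.287 ± 0.25 in DF. Of 38 dermal papilla markers, which name the sorted population, 34 were higher in DP and 1 was lower (camera adjusted p = 8.62e-07, and adjusted p = 0.677 with an estimated correlation). Beside these, stress genes were higher for 18 of 33 and lower for 1, or 6 and 2 with median-ratio scaling, and did not pass (adjusted p = 0.118). The stress list passed with no filter (adjusted p = 0.0137, within a range up to 0.317) and had adjusted p = 0.767 with an estimated correlation. Keratinocyte markers were higher for 8 of 29 and lower for 0, or 2 and 0 with median-ratio scaling, and did not pass (adjusted p = 0.814).

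Of 46 Wnt pathway genes, 28 were higher in DP and 3 lower, or 20 and 8 with median-ratio scaling. The extracellular inhibitors Notum, a lipase that removes the lipid of Wnt proteins, and Wif1 averaged 405 ± 48 and 486 ± 57.7 RPKM in DP against 6.47 ± 1.76 and 9.84 ± 3.02 in DF (log2 differences 5.78 and 5.51, both with adjusted p = 0.00011). The list did not pass as deposited (camera adjusted p = 0.0832) and passed with median-ratio scaling (0.000617), no filter (0.0313), a filter at 5 RPKM (0.0347), without Mir6236 (0.0337) and without the 100 highest genes in the total (0.00332), as adjusted p within a range up to 0.192. Its adjusted p = 0.919 with an estimated correlation. BMP and TGF-beta genes were higher for 19 of 38 and lower for 4, or 13 and 10 with median-ratio scaling, and did not pass (adjusted p = 0.855). Inhba, a subunit of activin, averaged 2318 ± 282 RPKM in DP and 70.0 ± 28.5 in DF (log2 difference 5.08, adjusted p = 0.000291), and Gdf10 (5.43) and Bmp3 (5.33) were higher too. Hedgehog and Notch genes were higher for 17 of 25 and lower for 1. The hedgehog targets Hhip (4.47) and Gli1 (4.03) were higher, and the hedgehog co-receptor gene Cdon was lower (-4.30). The test of that list was at the edge (camera adjusted p = 0.0465, and adjusted p = 0.767 with an estimated correlation). It ended without DF replicate 1 (0.0575), DF replicate 2 (0.136) or DP replicate 2 (0.0765), with pseudocount 0.1 (0.0792), with a filter at 5 RPKM (0.144) and after rescaling to equal sums (0.104), as adjusted p, within a range from 0.0012.

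Most matrix genes and reticular fibroblast markers were lower in DP than in DF, and papillary fibroblast markers went both ways. Col1a1 averaged 200 ± 27.8 RPKM in DP and 32801 ± 3934 in DF (log2 difference -7.35, SE 0.16, adjusted p = 3.4e-05), and Dcn, the small proteoglycan decorin, averaged 7.72 ± 2.38 and 3654 ± 106 RPKM (-8.74, SE 0.21, adjusted p = 4.45e-05). Mfap4 (-8.64), Lum (-8.47) and Col1a2 (-7.49) were also lower. Of 43 genes for fibrillar collagens and interstitial matrix, 4 were higher and 30 lower (camera adjusted p = 3.61e-30, and adjusted p = 0.145 with an estimated correlation). Reticular, fascial and adventitial fibroblast markers were higher for 1 of 25 and lower for 18, among them Pcolce2 (-7.24), Ly6a (-7.06) and Clec3b (-6.61), with camera adjusted p = 1.56e-21 and adjusted p = 0.0507 with an estimated correlation. Papillary fibroblast markers were higher for 9 of 17 and lower for 6, or 6 and 6 with median-ratio scaling. Their median was 1.49, and the list did not pass (camera adjusted p = 0.47). Crabp1, Prdm1 and Wif1, among the higher ones, are also on the dermal papilla list, so these lists are not independent. Matrix proteases and inhibitors were higher for 7 of 30, including Serpine2, and lower for 13, including Mmp27 (-7.03) and Mmp23 (-4.72), or 2 and 17 with median-ratio scaling, with camera adjusted p = 3.44e-08 and adjusted p = 0.195 with an estimated correlation. Leukocyte markers moved with these genes, higher for 3 of 19 and lower for 9, such as C1qc (-3.09), with camera adjusted p = 2.79e-06 and adjusted p = 0.404 with an estimated correlation. Melanocyte markers were higher for 2 of 12 and lower for 4, such as Trpm1 (-2.74) and Dct (-2.61), or 1 and 7 with median-ratio scaling, with camera adjusted p = 0.00311 and adjusted p = 0.677 with an estimated correlation. The melanocyte call ended without DF replicate 1 (adjusted p = 0.182), without DF replicate 2 (adjusted p = 0.217) and with median-ratio scaling (adjusted p = 0.0698), within a range from 0.000546.

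Contractile genes did not set DP apart from DF as a list, with 13 of 34 higher and 4 lower, or 7 and 6 with median-ratio scaling (camera adjusted p = 0.855). Mylk was lower in DP at 3.10 ± 0.494 RPKM (log2 difference -3.73, adjusted p = 0.000224), and Acta2 averaged 3.70 ± 0.188 RPKM in DP, which did not reach the log2 minimum of 1 (0.54, adjusted p = 0.0264) and was -0.09 with median-ratio scaling. Ednrb was higher in DP at 16.3 ± 2.37 RPKM (log2 difference 2.03, SE 0.20, adjusted p = 0.00104), while Ednra averaged 22.7 ± 0.3 RPKM in DP and did not pass (0.35, adjusted p = 0.0606, and -0.46 with median-ratio scaling).

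In all, 5620 of the 14664 genes differed between DP and DF, 4613 higher and 1007 lower in DP, and 9518 had an unadjusted p under 0.05. With median-ratio scaling 3279 genes differed, 1368 higher and 1911 lower, of which 1368 and 1003 had the same call as in the deposited scaling. Of the 31 lists, 2 were called up and 5 down, and none kept its call with an estimated correlation, where 3 had an unadjusted p under 0.05. Adjusted over the list alone, the counts of the lists above were the same. Among the 100 largest called differences, 45 were of small RNA genes.

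**Figure D2:**
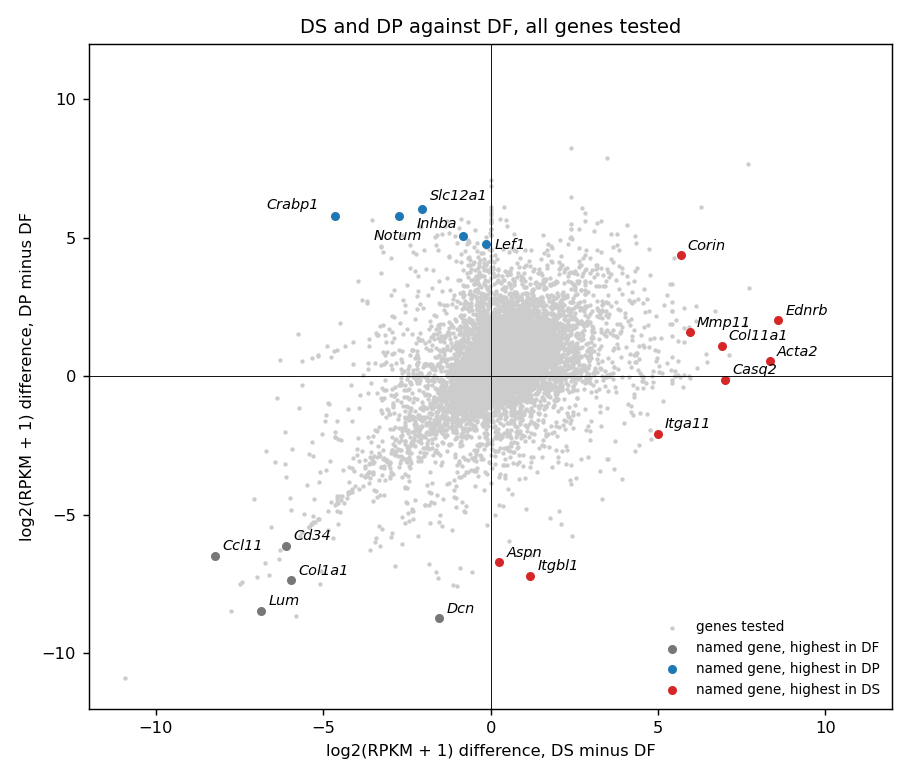
Log2(RPKM + 1) difference of DS minus DF on the x axis and of DP minus DF on the y axis for the 14664 genes tested, with named genes coloured by the population in which they were highest. Acta2 lies at 8.33 and 0.54, Crabp1 at -4.65 and 5.80, and Col1a1 at -5.96 and -7.35.

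DS was compared with DP to ask what distinguishes the mesenchymal layers of the follicle itself. More contractile genes were higher in DS than were lower. Acta2 averaged 1042 ± 79.8 RPKM in DS and 3.70 ± 0.188 in DP, a log2 difference of 7.79 (SE 0.15, adjusted p = 3.13e-05). Myl9, a regulatory light chain of myosin, averaged 674 ± 38.5 RPKM in DS and 9.30 ± 0.669 in DP (log2 difference 6.04, SE 0.13, adjusted p = 3.13e-05), and Actg2 (7.17), Casq2 (7.14) and Mylk (6.11) were higher too. Of 34 contractile genes, 23 were higher in DS and 2 lower (camera adjusted p = 4.64e-12, and adjusted p = 0.332 with an estimated correlation), and of 20 dermal sheath markers 18 were higher and 0 lower (camera adjusted p = 1.41e-13, and adjusted p = 0.277 with an estimated correlation). Beside these, 6 of 10 arrector pili muscle markers were higher, such as Npnt (5.15) and Synpo2 (5.03), and 3 were lower, such as Nrg2 (-4.65), with camera adjusted p = 0.0273 and adjusted p = 0.385 with an estimated correlation. The arrector pili call ended without DS replicate 1 (adjusted p = 0.388), without DS replicate 2 (adjusted p = 0.265) and with median-ratio scaling (adjusted p = 0.0735), within a range from 0.00359. Pericyte and vascular smooth muscle markers were higher for 3 of 16 and lower for 4 (adjusted p = 0.98).

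Both endothelin receptors were higher in DS than in DP, with log2 differences of 6.56 for Ednrb (SE 0.20, adjusted p = 4.09e-05) and 3.34 for Ednra (SE 0.13, adjusted p = 7.29e-05). The ligands went in opposite directions. Edn3 averaged 15.6 ± 3.5 RPKM in DP and 0.101 ± 0.102 in DS (log2 difference -3.90, adjusted p = 0.000321), and Edn1 averaged 3.99 ± 0.436 in DS and 0.770 ± 0.276 in DP (1.50, SE 0.30, adjusted p = 0.0158). The Edn1 call ended without DP replicate 1 (adjusted p = 0.0905), DP replicate 2 (adjusted p = 0.0528), DS replicate 1 (adjusted p = 0.0557) or DS replicate 2 (adjusted p = 0.0711), within a range from 0.00917. Of 10 endothelin genes, 5 were higher and 2 lower, or 5 and 1 with median-ratio scaling (camera adjusted p = 0.0274, and adjusted p = 0.406 with an estimated correlation). That call ended without DP replicate 1 (adjusted p = 0.0632), with median-ratio scaling (adjusted p = 0.0735) and with a filter at 5 RPKM (adjusted p = 0.0976), within a range from 0.0176.

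More fibrillar and interstitial matrix genes were higher than lower in DS against DP. Among the largest differences, Itgbl1 averaged 518 ± 6.53 RPKM in DS and 0.579 ± 0.163 in DP (log2 difference 8.36, SE 0.13, adjusted p = 2.55e-05). The proteoglycan genes Ogn (8.18), Prelp (7.43), Dcn (7.20) and Aspn (6.97) were higher, as were Mgp, an inhibitor of calcification (7.61), and Igfbp2 (7.65). Of 43 genes for fibrillar collagens and interstitial matrix, 23 were higher and 10 lower (camera adjusted p = 1.09e-06, and adjusted p = 0.385 with an estimated correlation). Matrix proteases were higher for 15 of 30, with Mmp13 at 23.4 ± 7.64 RPKM in DS and listed at 0 in both DP libraries and Mmp11 higher by 4.36, and lower for 7, with Mmp3 at -5.43 (camera adjusted p = 0.000263, and adjusted p = 0.332 with an estimated correlation). Reticular, fascial and adventitial fibroblast markers were higher for 9 of 25, with Mfap5 and Ly6a both at 6.51, and lower for 4 (camera adjusted p = 0.00624, and adjusted p = 0.332 with an estimated correlation). Papillary fibroblast markers were higher for 5 of 17 and lower for 9 and did not pass (adjusted p = 0.38).

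Most dermal papilla markers were lower in DS than in DP. Crabp1 averaged 0.853 ± 0.651 RPKM in DS and 2519 ± 235 in DP, a log2 difference of -10.45 (SE 0.38, adjusted p = 6.29e-05). The prolactin receptor gene Prlr (-8.52), Notum (-8.50), the ion transporter gene Slc12a1 (-8.09) and Enpp2, which encodes the lysophospholipase autotaxin (-7.96), were also lower. Of 38 dermal papilla markers, 6 were higher and 28 lower (camera adjusted p = 2.02e-08, and adjusted p = 0.385 with an estimated correlation). Of 46 Wnt pathway genes, 3 were higher and 24 lower, or 6 and 23 with median-ratio scaling, with the agonist Rspo4 at -7.94 and the inhibitors Sostdc1 at -7.69 and Sfrp1 at -6.60 (camera adjusted p = 3.9e-05, and adjusted p = 0.49 with an estimated correlation). BMP and TGF-beta genes were higher for 5 of 38 and lower for 17, such as Gdf10 (-6.80), Bmp7 (-6.55) and Bmp4 (-6.41), with camera adjusted p = 0.00641 and adjusted p = 0.698 with an estimated correlation. Stress genes were higher for 3 of 33 and lower for 19, such as Socs3 (-3.80), Hspa1a (-3.43) and Ier3 (-3.34), with camera adjusted p = 3.9e-05 and adjusted p = 0.332 with an estimated correlation.

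In all, 3257 of the 14664 genes differed between DS and DP, 1381 higher and 1876 lower in DS, and 6547 had an unadjusted p under 0.05. With median-ratio scaling 3128 genes differed, 1689 higher and 1439 lower, of which 1373 and 1439 had the same call as in the deposited scaling. Of the 31 lists, 7 were called up and 5 down, and none kept its call with an estimated correlation, where 3 had an unadjusted p under 0.05. The call not given above was of hedgehog and Notch genes, higher for 3 of 25 and lower for 10 (adjusted p = 0.0417, and adjusted p = 0.698 with an estimated correlation). It ended without DF replicate 1 (0.06), DF replicate 2 (0.0593), DP replicate 2 (0.107) or DS replicate 1 (0.0586) and in 6 other alternatives besides the estimated correlation, as adjusted p within a range from 0.0124 to 0.119 apart from it. Adjusted over the list alone, the counts of the lists above were the same except 6 higher endothelin genes and 11 lower hedgehog and Notch genes. Among the 100 largest called differences, 26 were of small RNA genes.

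**Figure D3:**
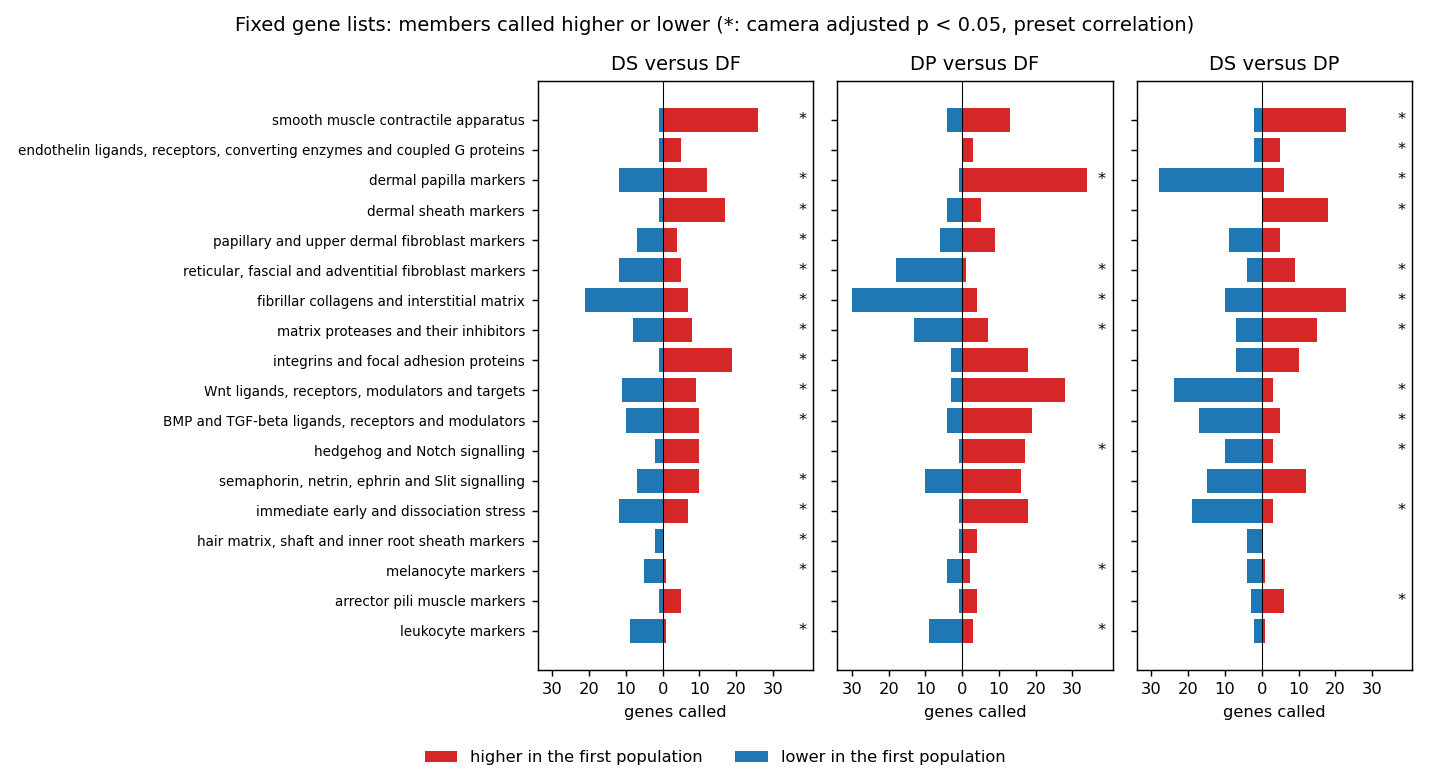
Number of genes called higher (red, to the right) or lower (blue, to the left) in the first population of each comparison, for each fixed list called in at least 1 comparison, with an asterisk where camera gave an adjusted p under 0.05 with the preset correlation. The contractile list has 26 genes higher for DS versus DF, 13 for DP versus DF and 23 for DS versus DP.

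Genes higher in a population than in both others numbered 884 in DS, 1484 in DP and 500 in DF. Those of DS with the largest smaller difference included Acta2, Actg2, Casq2, Ednrb, Pde6h, Palm3 and Fhl2, a LIM domain protein. Palm3 averaged 69.8 ± 2.82 RPKM in DS, 0.106 ± 0.0969 in DP and 0.141 ± 0.0331 in DF, and Fhl2 averaged 139 ± 17.5 RPKM in DS and 0.589 ± 0.0643 in DF. Slc12a1, Crabp1 and Notum led the protein-coding genes of DP, with Slc12a1 at 280 ± 26.4 RPKM in DP, 3.23 ± 0.369 in DF and 0.0293 ± 0.0105 in DS. Cpz, Pcolce2, Lum and C1qtnf3 led those of DF, with Cpz at 383 ± 73.6 RPKM in DF, 0.071 ± 0.0404 in DP and 0.769 ± 0.4 in DS. Independent lists of the same sizes would share 285, 590 and 60 genes. The 20 simulated data sets with no effect gave 0. They held a mean of only 0.05 calls for DS versus DF, so that 0 tells nothing about the effect of shared libraries. The comparisons of a population share its libraries, and what part of the excess over independent lists comes from that was not tested. With median-ratio scaling the numbers were 698, 838 and 914, of which 639, 838 and 500 were enriched in both scalings. All 3 numbers depended on single libraries, and that for DS fell most without DS replicate 2. The number for DP fell to 831 without DP replicate 1 and to 908 without DP replicate 2, and that for DF to 309 without DF replicate 1 and to 290 without DF replicate 2.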

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

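Rescaling without Mir6236 or without the 100 highest genes, and leaving out small RNA genes, were chosen after the data were seen. For the genes described or drawn in a figure, 2852 values under the alternatives kept their direction and call status, 33 lost the call, 10 gained it and 24 changed sign. For the lists these numbers were 825, 76, 35 and 18. Of the genes called in a comparison and still tested when a library was left out (2991 of 3257 for DS versus DP without a DP library), 0 changed sign, but many lost the call. The genes had been selected on these same libraries, so a change of sign was unlikely beforehand. Without DP replicate 1, 2124 of 2991 kept it for DS versus DP, and without DF replicate 1, 2694 of 3721 for DS versus DF. There the lone library of its population is assumed to vary like the others. Rescaling every sample to the same sum gave 6309 genes for DS versus DF, 9108 for DP versus DF and 313 enriched in DF. Median-ratio scaling gave 3279 for DP versus DF, 838 enriched in DP and 914 in DF, and scaling without the 100 highest genes gave 3631 and 872 enriched in DF. Each scaling moves all genes of a library together, and which scale is right was not tested. Without a fold minimum, which by construction adds calls, 6558 and 8642 genes differed from DF and 1464 and 2327 were enriched, for DS and DP. No filter on low values gave 11 lists for DP versus DF, and an estimated correlation gave 0 lists for DS versus DF, 0 for DP versus DF and 0 for DS versus DP, for which the cause was not tested. With a library left out, genes enriched in DP ranged from 831 to 1528 and those in DF from 290 to 484, with fewer samples behind each call.

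Changes of sign concerned differences not called as deposited, and their cause was not tested. For DP minus DF, Acta2 was -0.09 with median-ratio scaling. Under median-ratio scaling and without the 100 highest genes, Ednra was -0.46 and -0.29, Tagln -0.16 and -0.11, and Edn1 -0.39 and -0.40. Pdgfra, at 0.10 as deposited, was -0.74 with median-ratio scaling (adjusted p = 0.0048, in a range up to 0.864), -0.56 without the 100 highest genes and -0.17 without Mir6236. Edn1 was -0.14 without Mir6236. With a library left out, Pdgfra ranged from -0.10 to 0.31, Tagln from -0.30 to 0.91 and Edn1 from -0.37 to 0.37. Palm3 was 0.01 after rescaling to the same sum and ranged from -0.14 to 0.04 with a library left out. For DS minus DF, Lef1 was 0.29 after rescaling to the same sum and ranged from -0.54 to 0.26 with a library left out, where Alpl ranged from 0.00 to 0.40. Aspn was -0.38 with median-ratio scaling, -0.05 without Mir6236 and -0.35 without the 100 highest genes.

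The contractile list for DP versus DF turned with adjusted p of 0.72 without a filter, 0.82 with median-ratio scaling, 0.938 without Mir6236 and 0.868 without the 100 highest genes, and ranged from 0.793 to 0.977 with a library left out. Pericyte markers turned for DS versus DF at 0.721 with median-ratio scaling and 0.752 without the 100 highest genes. For DS versus DP they turned at 0.996 without a filter, 0.818 with a filter at 5 RPKM, 0.904 after rescaling to the same sum, 0.983 with only the 2 groups compared and 0.981 without Mir6236, and ranged from 0.423 to 0.955 with a library left out. Melanocyte markers turned for DS versus DP at 0.572 with a filter at 5 RPKM. Papillary fibroblast markers turned for DP versus DF at 0.782 with median-ratio scaling and 0.953 without the 100 highest genes. Keratinocyte markers turned for DP versus DF without DF replicate 2 (0.736) and ranged from 0.365 to 0.99 with a library left out.

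Among drawn genes, Itga8 for DP versus DF lost its call in 9 alternatives, including without DF replicate 1 (0.142), DP replicate 2 (0.159), DS replicate 1 (0.0562) or DS replicate 2 (0.0547), with adjusted p from 0.00882 to 0.314. Col11a1 for DP versus DF lost it without DF replicate 1 (0.0832) or DP replicate 1 (0.099), with median-ratio scaling (log2 difference 0.44), without the 100 highest genes (0.67) and without Mir6236 (0.98), with adjusted p from 0.00211 to 0.233. Myh11 for DS versus DP lost it without DP replicate 2 (0.0946), DS replicate 1 (0.104) or DS replicate 2 (0.0797) and after rescaling to the same sum (log2 difference 0.95), with adjusted p from 0.0152 to 0.104, and Cnn1 without DP replicate 1 (0.0793) or DP replicate 2 (0.0813), from 0.00926 to 0.0813. With median-ratio scaling and without the 100 highest genes, Mmp11 for DP versus DF (log2 differences 0.75 and 0.94) and Itgbl1 for DS versus DF (0.54 and 0.57, and 0.88 without Mir6236) fell under the log2 minimum. Lower Rspo3 and Inhba for DS versus DF gained a call under these scalings (-1.35 and -1.44 with median-ratio scaling) and without DF replicate 1 (-1.22 and -1.24), as did Rspo3 with pseudocount 0.1 and Ednra for DP versus DF after rescaling to the same sum.

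Among 268 further gene differences and 40 further list tests, covered by the naming rule but not described, 24 and 81 values changed sign, at adjusted p of at least 0.326 and 0.311. No shared effect of the replicate number was seen, as deviations of equal numbers correlated across genes at -0.046, -0.071 and -0.034. This does not settle whether the libraries are paired. A replicate block gave 3838, 5591 and 3163 genes. With it camera called keratinocyte markers down for DS versus DF (adjusted p = 0.0477) and DS versus DP (adjusted p = 0.0327). Depth limits low values most in DS.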

Other observations

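The tests of explanations below, other than that of small RNA genes, the rescalings without Mir6236 or the 100 highest genes, and the removal of small RNA genes were chosen after the result was seen, while the list and gene tests were fixed before. Some receptor genes of contracting or relaxing ligands differed by population. F2r, a thrombin receptor, averaged 214 ± 13.1 RPKM in DS and 9.04 ± 0.0544 in DF (SD, n = 2 libraries per population, log2 difference 4.42, adjusted p = 0.000344), and S1pr3, a sphingosine 1-phosphate receptor, and Ptger3, a prostaglandin receptor, were higher by 4.56 and 3.74. Avpr1a, a vasopressin receptor, averaged 266 ± 22.7 RPKM in DP, 5.30 ± 1.45 in DF and 0.429 ± 0.161 in DS, and the prostacyclin receptor gene Ptgir averaged 34.6 ± 5.4 RPKM in DP, 0.381 ± 0.00471 in DF and 0.253 ± 0.0275 in DS. The list had 9 of 29 genes higher and 8 lower for DS versus DF (adjusted p = 0.0568), 10 and 6 for DP versus DF (adjusted p = 0.29) and 7 and 7 for DS versus DP (adjusted p = 0.65). It was called down for DS versus DF with pseudocount 0.1 (0.0488), no filter (0.00573) and rescaling to equal sums (0.0254), and for DP versus DF with no filter (0.0321), as adjusted p within ranges up to 0.721 and 0.999 that leave out the estimated correlation, here and below. With an estimated correlation it had adjusted p = 0.47 for DS versus DF and adjusted p = 0.919 for DP versus DF. With median-ratio scaling 7 were higher and 10 lower for DS versus DF and 7 and 7 for DP versus DF. For DS versus DF camera placed it below the other genes although its median was 0.35 and its mean 0.62. Among cell death regulators, Bcl2, which blocks apoptosis, averaged 197 ± 18.7 RPKM in DP, 13.2 ± 1.85 in DF and 18.2 ± 0.142 in DS (log2 difference 3.80 for DP minus DF, SE 0.16, adjusted p = 0.000117). That list had 15 of 29 genes higher and 0 lower for DP versus DF and was not called (adjusted p = 0.126). With median-ratio scaling 5 were higher and 1 lower, and with no filter the list was called up (adjusted p = 0.0455, in a range up to 0.226), with adjusted p = 0.919 with an estimated correlation.

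Guidance genes went both ways between DS and DF. Sema3d averaged 218 ± 12.2 RPKM in DS and 6.91 ± 0.759 in DF (log2 difference 4.79, adjusted p = 9.17e-05) and Slit2 averaged 931 ± 67.8 and 78.1 ± 17.4 RPKM (3.57, adjusted p = 0.000159), while Sema3b was lower (-3.46). Of 39 genes 10 were higher and 7 lower, or 9 and 12 with median-ratio scaling, with a median of -0.12 and a mean of 0.30, and camera placed the list below the other genes (adjusted p = 0.0411, and adjusted p = 0.539 with an estimated correlation). The call ended without DF replicate 1 (0.0892), DP replicate 1 (0.0881), DP replicate 2 (0.0885), DS replicate 1 (0.051) or DS replicate 2 (0.0741) and with median-ratio scaling (0.253), without the 100 highest genes in the total (0.214) or Mir6236 (0.0644), with no filter (0.0747) and with only the 2 groups compared (0.0506), as adjusted p within a range from 0.0257. Hair matrix, shaft and inner root sheath markers were lower in DS than in DF for 2 of 27 genes, Lgr5 (-2.44) and Selenbp1 (-1.46), and higher for 0, with a median of 0.02 and a mean of -0.02 (camera adjusted p = 0.0012, and adjusted p = 0.569 with an estimated correlation). Selenbp1 lost its call after rescaling to equal sums (-0.93, under the log2 minimum of 1). The call of the list ended without DS replicate 1 (adjusted p = 0.574), with median-ratio scaling (adjusted p = 0.116) and without the 100 highest genes in the total (adjusted p = 0.0793), within a range from 3.38e-09. Keratinocyte markers were not called, with 2 of 29 higher and 0 lower for DS versus DF (adjusted p = 0.0535) and 0 higher and 5 lower for DS versus DP (adjusted p = 0.051), with 1 higher and 1 lower, then 1 higher and 2 lower, under median-ratio scaling. They were called down for DS versus DF without DF replicate 2 (0.00248), DP replicate 1 (0.045), DP replicate 2 (0.0448) or DS replicate 2 (0.00255) and with rescaling to equal sums (0.0372), pseudocount 0.1 (0.048), only the 2 groups compared (0.0466) or no small RNA genes (0.0444), and for DS versus DP without DP replicate 1 (0.00955) or DS replicate 2 (0.00192) and with median-ratio scaling (0.0367), no filter (0.0397), no trend (0.0426) or no small RNA genes (0.048), among other alternatives, as adjusted p within ranges up to 0.65 and 0.426. With an estimated correlation they had adjusted p = 0.624 for DS versus DF and adjusted p = 0.977 for DS versus DP.

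Of the genes called against DF, 77.6% were higher in DS and 82.1% in DP. Medians over all genes were taken for the 8 pairs of a DS or DP library with a DF library, and lay from 0.39 to 0.84 as deposited. After rescaling every library to the same sum without Mir6236 the smallest was 0.21. Some shift thus remained. The share of Mir6236 in the reads was not computed, since the transcript length behind its RPKM is not given in the sources used here. Its part was therefore not settled. Without the 100 highest genes the 4 medians of DS and DF pairs lay from -0.01 to 0.08. Those of DP and DF pairs fell from 0.58 to 0.84 to values of 0.12 to 0.22, so part of the DP shift remained. Division by a sum removes any factor common to a library. These values therefore cannot tell abundant transcripts of DF from another cause of such a factor. The depth estimates argue against lower depth in DF. The lowest relative depth of a DF library was 0.71 and the highest of the others 0.63, with no uncertainty computed. RPKM are divided by library depth, so a difference in the total amount of RNA per cell cannot be seen in them and was not tested.

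Cells of another type in the DS sort may contribute to Ednrb and the contractile genes, and whether the gate removes them is not given in the sources used here. Melanocytes are excluded as the whole source of Ednrb, since the 12 tested melanocyte markers had a median log2 difference of -1.04 (SD 1.26) for DS minus DF and -0.23 (SD 1.17) for DS minus DP, against 8.58 and 6.56 for Ednrb. Pericytes or vascular smooth muscle cannot be told apart from DS cells as a source of the contractile genes, because the 16 markers went both ways, with medians of 0.65 (SD 2.87) and -0.39 (SD 3.23) for DS minus DF and DS minus DP, against 2.21 and 1.9 for the contractile list. Of them Casq2 and Mcam were abundant in DS, at 147 ± 2.98 and 105 ± 6.57 RPKM, and Kcnj8 and Abcc9, chosen after their values were seen, averaged 0.494 ± 0.699 and 1.08 ± 0.339 RPKM there. Arrector pili muscle cannot be told apart either, as its 6 markers outside the contractile list had medians of 1.86 (SD 2.40) and 1.02 (SD 3.93), and contraction genes made by DS cells themselves stay open as untested.

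Small RNA genes made up 34, 45 and 26 of the 100 largest called differences for DS versus DF, DP versus DF and DS versus DP, and 65, 98 and 74 of the 397 tested were called. Their short length, which turns few reads into a high RPKM, is a candidate explanation. In 32.3% of combinations of a small RNA gene and a population, 1 replicate was at 0 and the other at 5 RPKM or more, against 0.0981% for other genes, a ratio of 329, as short length would give. Differences between the populations in these RNAs stay open, since library methods for small RNA were not used here.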
